A study of Mus musculus with 4 samples.

How the data were processed

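The assay was ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, so that reads pile up where DNA is accessible. It was applied to 4 libraries of CD8+ T cells from lymph nodes of 8-week-old female mice. Per the labels, naive cells were stimulated for 12 h with anti-CD3 and anti-CD28 antibodies, each at 1 µg/ml, which engage the T cell receptor and a co-stimulatory receptor. The KO group (2 libraries) came from mice with a loxP-flanked Atf4 gene and a Cre recombinase driven by Cd4 sequence. The WT group (2 libraries) carried the loxP-flanked gene without Cre. The labels describe the libraries of a group as biological replicates.

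The submitters' processing notes name Genrich, DiffBind 3.12.0 and ChIPseeker 1.38.0, without saying what each was used for, and name both GRCm38 and GRCm39. The aligner and the read filters, including any shift of reads for the transposase cut, are not given in the sources used here. The 1 file analysed was a table of the authors' own comparison of KO with WT, whose name gives DESeq2 as the test. It lists 47048 peaks, of which 47024 are 401 bp wide, in 1 peak set shared by both groups. For each peak the authors deposited log2 values of the mean normalized reads over all libraries, over KO and over WT, and a log2 fold of KO over WT. They also deposited a p-value and a false discovery rate (FDR). The scale was tested on the values: the overall mean equalled the log2 of the average of both group means at every peak, with a largest gap of 9.6e-14. The deposited FDR equalled a Benjamini-Hochberg adjustment of the deposited p over all peaks, with a largest gap of 1.4e-14. The method of normalization is not given in the sources used here.

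The deposited fold was smaller in size than the difference of the group means at 99.9% of peaks. Its median ratio to that difference was 0.702 at peaks with an FDR under 0.05 and 0.0922 at the others, so it is a moderated value that understates the difference most where the evidence is weak. Group means are therefore printed beside folds, as normalized reads per library averaged by the authors. The table holds no values per library, so read depth per library is unknown, and no standard deviation or test could be computed from library values. Where a bound is given for a difference, it rests on the spread implied by the deposited p. The differential test is the authors' own, with a threshold of 0.05 on their FDR.

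Peaks were placed on genes with the RefSeq annotation of GRCm38.p6, using its 21896 protein-coding genes. The build of the peaks was checked by their distance to gene ends. Of the peaks, 23.1% lay within 1 kb of a gene end, against 6.45% and 6.49% after all peaks were shifted by 50 kb up or down. The share was above both shifted values on each of 20 chromosomes. Coordinates are GRCm38, counted from 1. The annotation gives gene spans without strand or exons, so a gene's start could not be told from its finish. The planned promoter class was replaced by a gene-end class: a peak centre within 3 kb of either end of a protein-coding gene. Other peaks were inside a gene span or intergenic. Each peak was assigned to the protein-coding gene whose span holds it or, failing that, whose end is nearest; an assignment is a position, not a regulatory link.

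The share of gene-end peaks among called peaks was compared with uncalled peaks by two-sided Fisher's exact tests, and within classes of mean signal by an exact conditional test with a Mantel-Haenszel odds ratio. For 16 gene lists fixed before the data were examined, the median deposited fold of gene-end peaks was placed among 10000 random sets of gene-end peaks of the same size, matched on 10 classes of mean signal. This gave a two-sided permutation p, adjusted over the 16 lists by Benjamini-Hochberg, whose smallest value before adjustment is 0.0002. List medians and ranges of random sets are printed as differences of log2 group means, a scale added after the data were seen, beside the p from deposited folds. The lists covered ATF4 targets, amino acid transport, tRNA synthetases, the unfolded protein response (UPR) and autophagy, early activation, the naive state, effector genes, T cell receptor signalling, the cell cycle, glycolysis, mTORC1 with ribosome biogenesis, and markers of 5 other cell classes. Peaks are not replicates, and with no values per library the correlation between peaks could not be estimated, so these p-values describe the deposited libraries. The genes named were fixed by rule before the data were examined. Atf4 came first. Then came, in each direction, up to 10 genes with the largest fold among called peaks above the median signal, leaving out predicted gene models. Up to 4 called genes per list followed, or the 2 with the smallest p where no gene of a list was called. One result that this rule names is not reported here.

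Alternatives were other FDR thresholds, minimum folds, peak filters and adjustments, a 1 kb gene-end class and other set tests. Others subtracted a centre from the log2 difference and recomputed a Wald p, with the spread implied by each deposited p. On simulated tables of 47048 peaks with an offset of -0.14 and 200 changed peaks, centring recovered 3% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 1.5 on the log2 scale, with 1, 9 and 11 false calls. The simulated offset was the same at every peak, and 100 peaks rose and 100 fell. In the deposited data the offset varied with peak signal, so these rates may not carry over to the centred calls. In a simulation of the gene list test over 16148 gene-end peaks, 6 of 100 unchanged lists and 100 of 100 lists lowered by 0.02 on the scale of the deposited, moderated log2 fold had p under 0.05. Each simulated list held 40 peaks drawn independently and shifted alike. The lists used here hold several neighbouring peaks per gene, so these rates may not carry over to them. The motif comparison was left out because no genome sequence was used here. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.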

Results

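Chromatin accessibility was compared between ATF4-deficient (KO) and control (WT) CD8+ T cells after 12 h of stimulation through the T cell receptor. ATF4 is a transcription factor of the amino acid and integrated stress responses, and the series title places the comparison in a study of how its basal level bears on readiness to proliferate. The data were group means over 2 KO and 2 WT libraries at 47048 peaks, with a median of 195.5 normalized reads per peak and a range of 19.2 to 5142. No error bars accompany the group means, because no values per library were analysed. Summed over all peaks, the KO mean was 0.951 of the WT mean.

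Loss of ATF4 was accompanied by lower accessibility at most of the peaks that changed. In the authors' deposited table, a set of 658 peaks (1.4%) passed an FDR of 0.05, of which 639 were lower and 19 higher in KO. The lower peaks had a median of 105 normalized reads in KO against 205 in WT, and a median log2 fold of -0.65. The higher peaks had medians of 153 in KO and 58.5 in WT, and a median log2 fold of 0.87. Only 44 lower and 7 higher peaks had a deposited log2 fold of at least 1 in size. The whole distribution was displaced: 74.9% of all peaks had a lower mean in KO, and the median log2 difference was -0.14. After this median was subtracted, 202 peaks were lower and 43 higher, so that higher peaks went from 2.89% to 17.6% of the calls.

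**Figure D1:**
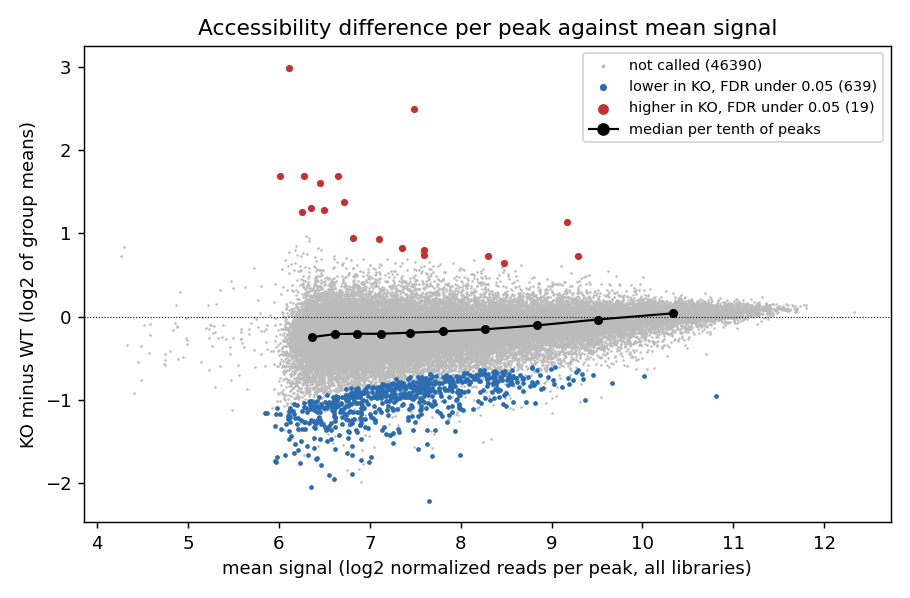
Each point is a peak, with the log2 mean normalized reads over all libraries on the x axis and the KO minus WT difference of log2 group means on the y axis. Blue points are the 639 peaks lower and red points the 19 peaks higher in KO at an FDR under 0.05, and the black line joins the medians of the 10 signal classes, which run from -0.25 in the weakest to 0.04 in the strongest.

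The displacement depended on peak strength. The median log2 difference was -0.25 in the weakest of 10 signal classes of equal size, at a median of 82.6 normalized reads, and 0.04 in the strongest class, at 1292 reads. The strongest class held 2 lower and no higher peaks, and the next class 10 lower and 1 higher, against 91 lower and 7 higher in the weakest. Lower peaks lay away from the ends of genes: 75 of 639 (11.7%) were within 3 kb of a protein-coding gene end, against 34.6% of uncalled peaks (odds ratio 0.251, two-sided Fisher's exact test, adjusted p = 9.2e-39 over 6 comparisons). A further 312 (48.8%) were inside gene spans and 252 (39.4%) were intergenic, against 38.3% and 27.1% of uncalled peaks, with adjusted p of 1.5e-07 and 6e-11 in the same test. Gene-end peaks were also the stronger ones, and with uncalled peaks matched on signal the odds ratio was 0.397 (exact conditional test within signal classes, two-sided p = 5.1e-17). Over all peaks, the median log2 difference was -0.06 at gene ends, -0.18 inside gene spans and -0.19 in intergenic stretches. The tests of place used calls without centring. They cannot tell a shift shared by peaks away from gene ends from falls particular to the called peaks. Of the 19 higher peaks 2 were at gene ends (odds ratio 0.222, adjusted p = 0.043 by Fisher's exact test), which did not hold against signal-matched peaks (odds ratio 0.334, exact conditional p = 0.18).

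The targeted gene, Atf4, spans positions 80255184 to 80257545 of chromosome 15. No peak within 10 kb of it was analysed here, so the deletion itself could not be checked. The nearest peaks analysed lay 29.2 kb below and 19.8 kb above the gene. Above it, 6 of the 19 higher peaks lay between 19.8 and 74.4 kb from Atf4, 1 of them 9918 bp outside and 5 inside the span of Cacna1i, which encodes a T-type calcium channel subunit. In the authors' deposited table the peak at 80277120 to 80277520 had 153 normalized reads in KO and 47.6 in WT, with a log2 fold of 1.31 and an FDR of 2.9e-06. The other 5 rose, from WT means between 30.5 and 52.7 reads to KO means between 98.4 and 132 reads in the authors' deposited table, with log2 folds from 0.80 to 1.17. Between these peaks 3 others were not called, and the one near the end of Cacna1i had 253 reads in KO and 251 in WT.

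The largest rises were at Cd4, the co-receptor gene of helper T cells, whose regulatory sequence drives Cre in the KO mice. Cd4 spans 124864693 to 124888247 of chromosome 6. The peak at its upper end, 124888035 to 124888435, had 303 normalized reads in KO and 54.1 in WT, with a log2 fold of 2.34 and an FDR of 3.9e-22 in the authors' deposited table. Inside the gene, the peak at 124880106 to 124880506 went from 15.4 to 122 reads (log2 fold 2.62, FDR 3.7e-12 in the authors' deposited table). The peak at 124885172 to 124885572 went from 360 to 789 reads (log2 fold 0.98, FDR 6.2e-08 in the authors' deposited table). Another peak, at 124900379 to 124900779 and 3.78 kb from Lag3, which encodes an inhibitory receptor, rose from 278.5 to 433 reads (log2 fold 0.49, FDR 0.037 in the authors' deposited table). The next peaks on both sides of these 4 were not called.

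**Figure D2:**
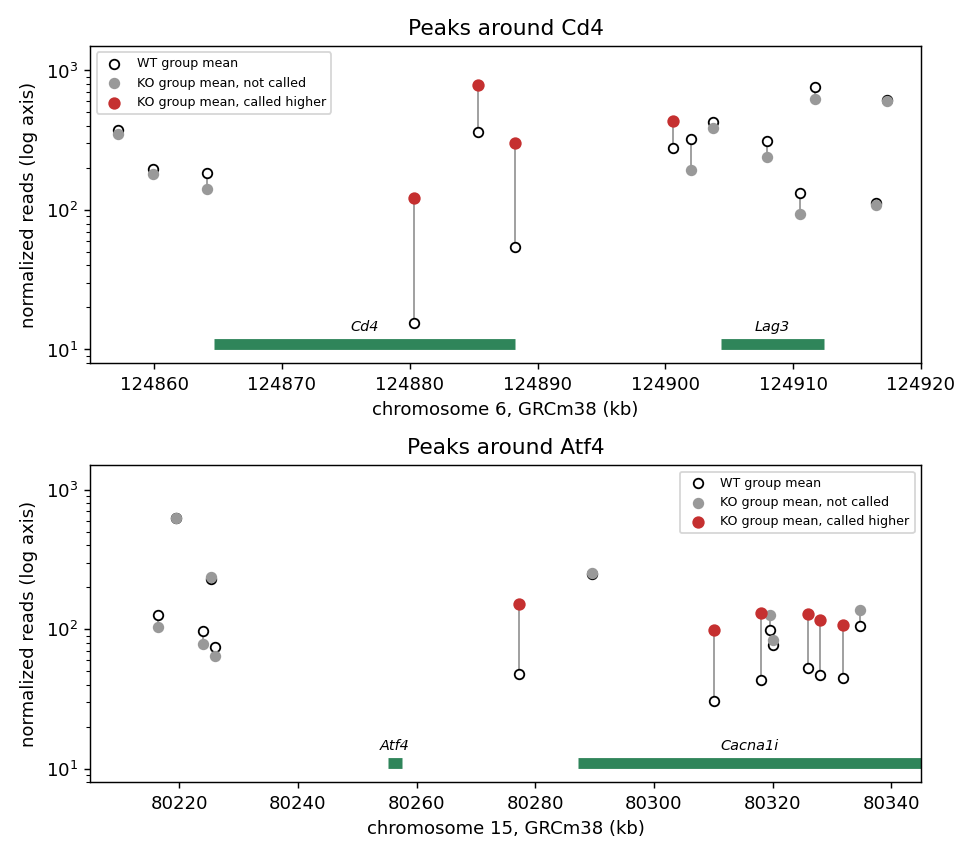
Group means of normalized reads (log axis) are plotted against GRCm38 position in kb around Cd4 (top) and Atf4 (bottom), with open circles for WT, filled circles for KO, red where the peak was called higher, and green bars for gene spans. At Cd4 4 neighbouring peaks are raised in KO, and 6 peaks beside Atf4 are raised with 3 uncalled peaks between them.

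Outside these loci, 2 further named genes had a called higher peak above the median signal. A peak 10.4 kb from Cxcr4, which encodes a chemokine receptor, rose from 238 to 392 normalized reads, with a log2 fold of 0.54 and an FDR of 0.033 in the authors' deposited table. A peak inside Tshz2, which encodes a zinc-finger transcription factor, rose from 473 to 782 reads, with a log2 fold of 0.52 and an FDR of 0.040 in the authors' deposited table. The calls at Tshz2 and at the peak near Lag3 ended when the FDR was computed over peaks at or above the median signal alone.

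Among lower peaks above the median signal, and with predicted gene models left out, the 10 genes with the largest falls were Cdk6, Ptpn1, Slc5a1, Zbtb18, Ptger4, C6, Cd200r3, Thrb, Retreg1 and Hes1. All 10 peaks were inside a gene span or intergenic, and their log2 folds in the authors' deposited table ran from -1.45 to -0.89. The peak inside Cdk6, a kinase that drives entry into the cell cycle, at 3477760 to 3478160 of chromosome 5, fell from 314 to 98.4 normalized reads (FDR 4.1e-10 in the authors' deposited table). The peak 20.6 kb from Ptpn1, which encodes a tyrosine phosphatase, at 167909990 to 167910390 of chromosome 2, fell from 385 to 122 reads (FDR 1.4e-10 in the authors' deposited table). The peak nearest Ptger4, which encodes a prostaglandin E2 receptor, fell from 285 to 111 reads but lay 358 kb away, and the peak nearest Hes1, which encodes a repressor of the Notch pathway, fell from 351 to 162 reads at 200.1 kb. A peak inside Thrb, the thyroid hormone receptor beta gene, fell from 294 to 134 reads, and one inside Retreg1, which encodes a receptor for autophagy of the endoplasmic reticulum, fell from 310 to 136 reads.

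Of the ATF4 targets, genes of amino acid synthesis and the stress response, 4 of 28 genes with a peak had a lower peak, none had a higher one, and 24 had neither. Of all peaks 1.36% were lower and 0.04% higher, so few higher peaks can be looked for in any list. Genes differ in their number of peaks, and the gene counts of this and the following lists were not tested against a background. The gene-end peak of Chac1, which encodes a glutathione-degrading enzyme, fell from 209 to 105 normalized reads (log2 fold -0.74, FDR 0.0036 in the authors' deposited table). The gene-end peak of Atf3, a stress-induced transcription factor gene, fell from 430 to 251 reads (log2 fold -0.59, FDR 0.019 in the authors' deposited table). A peak inside Mthfd2, an enzyme of mitochondrial one-carbon metabolism, fell from 149 to 78.8 reads (FDR 0.039), and one 50.8 kb from Bcat1, a branched-chain aminotransferase, fell from 133 to 53.8 reads (FDR 0.0012), in the authors' deposited table. The calls at Atf3 and Mthfd2 ended when the median difference was subtracted, and the call at Chac1 ended when the medians of peaks of like signal were subtracted. As a list the 36 gene-end peaks did not stand apart from random sets of like signal, with a median log2 difference of -0.06 and an adjusted permutation p = 0.42. With the mean fold, all assigned peaks or assigned peaks within 50 kb the list did lie below random sets, with adjusted permutation p of 0.021, 0.013 and 0.016. It did not pass with 1 gene-end peak per gene or with unmatched random sets, with adjusted permutation p of 0.22 and 0.95. The mean was not tested without the called peaks of Chac1 and Atf3. Of 58 assigned peaks away from gene ends 2 (3.45%) were lower, in a comparison chosen after the data were seen. That share lay inside the central range of 0% to 5.17% for random sets of like signal. Counted with the FDR adjusted over the list alone, 2 of the 36 peaks were called, and 2 over all peaks.

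None of the 15 genes of amino acid transport or the 20 tRNA synthetase genes with a peak had a called peak in the authors' DESeq2 test, and 5 and 2 of them had a peak at an unadjusted p under 0.05. The smallest p among transporters belonged to Slc7a5, the large neutral amino acid transporter, with 388 normalized reads in KO and 564 in WT (FDR 0.14 in the authors' deposited table), followed by Slc43a1 with 219 and 325 (FDR 0.14). A run of lower peaks in the region of Slc7a5, given under other observations, was not assigned to it. Among synthetases Gars had 290.2 reads in KO and 401 in WT (FDR 0.27) and Dars 201 and 262 (FDR 0.44) in the authors' deposited table. Adjusted over the list alone, no gene-end peak of either list was called, and their adjusted permutation p were 0.24 and 0.36. Of the UPR and autophagy genes 2 of 20 had a lower peak: the endoplasmic reticulum degradation gene Edem1, from 285 to 137 reads, and Gabarapl1, an autophagosome gene, from 118 to 49.5 reads, with FDR of 0.00032 and 0.0062 in the authors' deposited table. This list did not stand apart (adjusted permutation p = 0.93), and 1 of its 29 gene-end peaks was called adjusted over the list alone. The call at Gabarapl1 ended when the medians of peaks of like signal were subtracted.

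Genes induced early after T cell receptor stimulation were the list with the clearest fall. Of 34 genes, 8 had a lower peak, none a higher one and 26 neither. Over their 71 gene-end peaks the median log2 difference was -0.23, against a central range of -0.12 to -0.03 for random sets of like signal (adjusted permutation p = 0.0011 on deposited folds, from the smallest p the draws can give). After the shift of all peaks was subtracted the median was -0.10, against 0.01 to 0.10 for random sets, which move by the same amount. Adjusted over the list alone 10 of the 71 peaks were called, against 3 over all peaks. A gene-end peak of Cd44, an adhesion receptor of activated T cells, fell from 416 to 251 normalized reads (log2 fold -0.58, FDR 0.015 in the authors' deposited table). A peak 5.37 kb from Ifng, the interferon gamma gene, fell from 99.9 to 38.5 reads (FDR 0.0061), and one 22.8 kb from Icos, a co-stimulatory receptor gene, from 156 to 60.5 reads (FDR 0.00026), in the authors' deposited table. A peak 376 kb from Myc, a driver of growth and proliferation, fell from 137 to 58.7 reads (FDR 0.0019 in the authors' deposited table). The call at Cd44 ended when the median difference was subtracted, and the call at Ifng ended when the medians of peaks of like signal were subtracted. The list also passed with all assigned peaks, with assigned peaks within 50 kb, with the mean fold and with 1 peak per gene.

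Genes of the naive and quiescent state lay on the other side of their random sets. Their 53 gene-end peaks had a median log2 difference of 0.02 against a central range of -0.12 to -0.02 for random sets (adjusted permutation p = 0.0011 on deposited folds). With the shift subtracted from both, the median was 0.16 against 0.01 to 0.12. None of these gene-end peaks was called, over all peaks or adjusted over the list alone. Away from gene ends 5 of 25 genes had a lower peak and none a higher one. Of the 431 peaks assigned to the list there 6 (1.39%) were lower, in a comparison chosen after the data were seen. That share lay inside the central range of 0.464% to 3.02% for random sets of like signal. Peaks fell 25.2 kb from Ccr7, a lymph node homing receptor gene, from 607 to 295 normalized reads, and 13 kb from Klf3, from 226 to 116 reads, with FDR of 0.00033 and 0.0069 in the authors' deposited table. Peaks of the transcription factor genes Satb1, at 318 kb, and Bach2, within its span, fell from 190.4 to 100.2 reads and from 179 to 97.1 reads, with FDR of 0.019 and 0.037 in the authors' deposited table. The list's place above random sets did not hold with the mean fold (adjusted permutation p = 0.14) or assigned peaks within 50 kb (adjusted permutation p = 0.28), and with all assigned peaks the list lay at the 27.2 percentile (adjusted permutation p = 0.67). The calls at Klf3, Satb1 and Bach2 ended when the median difference was subtracted.

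T cell receptor signalling genes had lower peaks at 9 of 35 genes and higher peaks at none, and their 97 gene-end peaks had a median log2 difference of -0.14 against -0.11 to -0.03 for random sets (adjusted permutation p = 0.0011 on deposited folds). After the shift of all peaks was subtracted this median was 0.00, against 0.03 to 0.10 for random sets, which move by the same amount. Peaks inside Nfatc2, a calcium-dependent transcription factor gene, fell from 269 to 126 normalized reads and inside the kinase gene Fyn from 168 to 68.4, with FDR of 0.00034 and 0.0017 in the authors' deposited table. A peak inside Grap2, an adaptor gene, fell from 104 to 47.6 reads (FDR 0.023 in the authors' deposited table), a call that ended when the median difference was subtracted. Adjusted over the list alone 2 gene-end peaks were called, against 1 over all peaks. The list did not pass with the mean fold, 1 peak per gene, all assigned peaks or assigned peaks within 50 kb, with adjusted permutation p of 0.18, 0.26, 0.19 and 0.28. Of its 446 assigned peaks away from gene ends 11 (2.47%) were lower, in a comparison chosen after the data were seen. That share lay inside the central range of 0.673% to 3.14% for random sets of like signal.

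Of the effector and exhaustion genes 7 of 24 had a lower peak, and the higher peak in the run at Cd4 given above was assigned to Lag3 by position. The other peaks assigned to Lag3 were not called and had log2 differences from -0.74 to -0.16. Peaks fell 33.6 kb from Ctla4, an inhibitory receptor gene, from 261 to 128 normalized reads, and 9.24 kb from Il10ra, the interleukin-10 receptor gene, from 132 to 51.3, with FDR of 0.00065 and 0.002 in the authors' deposited table. Peaks nearest the transcription factor genes Prdm1 and Eomes fell from 159.8 to 72.1 reads and from 125 to 51.3 reads, with FDR of 0.0041 and 0.0053 in the authors' deposited table. The calls at Prdm1 and Eomes ended when the medians of peaks of like signal were subtracted. The 52 gene-end peaks of the list had a median log2 difference of -0.18 against -0.16 to -0.05 for random sets (adjusted permutation p = 0.03 on deposited folds). With the shift of all peaks subtracted from both, the median was -0.05 against -0.03 to 0.08. None of these gene-end peaks was called, also adjusted over the list alone. The list did not pass with 1 peak per gene, the mean fold or assigned peaks within 50 kb, with adjusted permutation p of 0.99, 0.58 and 0.28.

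Glycolysis genes had lower peaks at 3 of 21 genes and a median log2 difference of -0.15 over 39 gene-end peaks, against -0.12 to 0.00 for random sets (adjusted permutation p = 0.018 on deposited folds). With the shift of all peaks subtracted from both, this median was -0.02 against 0.01 to 0.14 for random sets. The list did not pass with the mean fold, 1 peak per gene or assigned peaks within 50 kb, with adjusted permutation p of 0.14, 0.29 and 0.064. A gene-end peak of Pgk1, a glycolytic kinase, at 106186825 to 106187225 of chromosome X, fell from 2369 to 1225 normalized reads (log2 fold -0.78, FDR 0.00028 in the authors' deposited table). The other gene-end peaks of Pgk1 were not called and had log2 differences of -0.39 and -0.25. Peaks fell inside Hk2, hexokinase 2, from 469 to 243 reads and 24.5 kb from Hif1a, the hypoxia-inducible factor gene, from 147 to 59.8 reads, with FDR of 0.0029 and 0.0024 in the authors' deposited table. Adjusted over the list alone 2 gene-end peaks were called, against 1 over all peaks. Cell cycle genes had a lower peak at 1 of 39 genes, Cdk6, and the mTORC1 and ribosome biogenesis genes at 1 of 28, a peak inside the S6 kinase gene Rps6kb1 that fell from 96.6 to 46.5 reads (FDR 0.049 in the authors' deposited table), a call that ended when the median difference was subtracted. Neither list stood apart, with adjusted permutation p of 0.47 and 0.81, and no gene-end peak of either was called adjusted over the list alone. With all assigned peaks the cell cycle list lay below random sets (adjusted permutation p = 0.008). It did not pass with assigned peaks within 50 kb, the mean fold or 1 peak per gene, with adjusted permutation p of 0.39, 0.82 and 0.63.

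**Figure D3:**
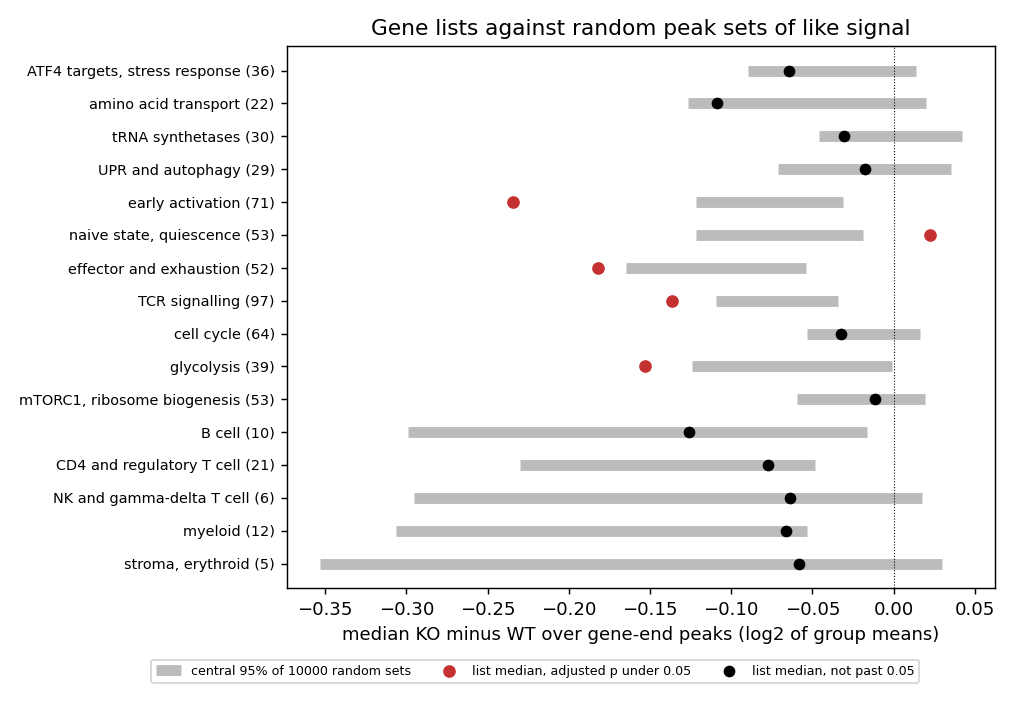
Points are the median KO minus WT difference of log2 group means (x axis) over the gene-end peaks of each fixed list (rows, number of peaks in parentheses), and grey bars are the central 95% of 10000 random sets of peaks of like signal. Red points are lists past an adjusted p of 0.05 in the test on deposited folds: early activation, effector, T cell receptor signalling and glycolysis genes lie below their bars and naive state genes above.

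Markers of other cell classes were examined because a lymph node preparation could hold them. No B cell, myeloid or stromal and erythroid gene had a called peak in the authors' DESeq2 test, among 10, 8 and 7 genes with peaks, of which 3, 0 and 2 had a peak at an unadjusted p under 0.05. The smallest p belonged to Cd22 with 262 normalized reads in KO and 392 in WT, and to Bank1 with 98.5 and 139, at FDR of 0.13 and 0.41 in the authors' deposited table. Among myeloid genes Zbtb46 had 120.4 and 165 reads and Itgam 283 and 222, at FDR of 0.45 and 0.49, and among stromal genes Epcam had 245 and 347 and Pecam1 150.3 and 224, at FDR of 0.18 and 0.23 in the authors' deposited table. Of the NK and gamma-delta T cell genes a peak inside Zbtb16 fell from 247 to 142 reads (FDR 0.043 in the authors' deposited table), a call that ended when the median difference was subtracted. Of 10 genes of CD4 and regulatory T cells, Cd4 alone had higher peaks, and a peak 55.4 kb from Gata3 fell from 249 to 127 reads (FDR 0.0015 in the authors' deposited table). Adjusted over the list alone, the called gene-end peaks of these 5 lists were the same number as over all peaks: 2, both at Cd4. Adjusted permutation p ran from 0.24 for the myeloid list to 0.81 for the B cell list. With all assigned peaks the myeloid and the NK and gamma-delta T cell lists lay above random sets, with adjusted permutation p of 0.012 and 0.011, and both did with assigned peaks within 50 kb (adjusted permutation p = 0.016). With the mean fold the CD4 and regulatory T cell list lay above random sets (adjusted permutation p = 0.0016), but not without the peaks of Cd4 (adjusted permutation p = 0.82).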

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

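The subtraction of the summed signal, of like-signal medians and of the strongest peaks' median, and the list tests on group means and without Cd4, were chosen after seeing the data. The 658 calls became 265 (254 lower, 11 higher) at an FDR of 0.01, 1064 (1028 and 36) at 0.1, 51 (44 and 7) with an absolute log2 fold of at least 1, 178 (176 and 2) among peaks at or above the median signal, and 188 (178 and 10) with Benjamini-Yekutieli adjustment. Centring left 245 (202 and 43) on the median of all peaks, 330 (306 and 24) on the summed signal, 183 (138 and 45) on peaks of like signal and 940 (921 and 19) on the strongest peaks; lower calls outnumbered higher calls in all of these. A minimum fold of 0.5, autosomes alone and recomputed Benjamini-Hochberg values kept the count within 1.5 times. The odds ratio of lower peaks at gene ends stayed below 1 and past the threshold in its 4 alternatives, none of which used centred calls, from 0.139 to 0.397. That of higher peaks lost the threshold with a 1 kb gene end (0.183), at an FDR of 0.01 (0.423) and against signal-matched peaks (0.334). In place of 5 lists, 3 passed with the mean fold (activation, ATF4 targets, CD4 and regulatory T cells), 2 with the mean fold and Cd4 left out (activation, ATF4 targets) and 2 with 1 gene-end peak per gene (activation, naive). With assigned peaks within 50 kb, 4 of the 5 lost the threshold, activation kept it, and the ATF4 target, NK and myeloid lists passed it. The naive list moved to the other side of its random sets with all assigned peaks (27.2 percentile), and the effector list with 1 peak per gene (50.6 percentile); the causes were not tested. Of 43 called named peaks none changed direction, and 9 lost their call when centred on the median, 15 when centred on like signal, among them Chac1, Prdm1, Eomes, Ifng and Gabarapl1. No paired analysis was possible because the table holds group means only, and for the same reason leaving out replicates, count-based tests and pseudocounts were not run. The motif and Atf4 locus comparisons were not run, for want of sequence and of peaks near Atf4 here. Read depth per library is unknown, so the depth below which differences go undetected cannot be given.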

Other observations

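All tests in this part were chosen after the results they bear on were seen. Some genes had several lower peaks, and those named here were chosen after their values were seen; whether this exceeds chance was not tested. Of 534 named genes nearest to a lower peak, 60 had at least 2 and 3 had at least 4. Myc, the growth regulator, had 6 lower peaks among the 62 assigned to it, and Ptger4 and Nabp1 had 4 each, among 19 and 21. Cdk6, Fyn, Bcl2, a survival gene, and Il2ra, the interleukin-2 receptor alpha gene, had 3 each, among 21, 36, 29 and 19 peaks, and none of these genes had a higher peak. Of the runs of lower peaks less than 20 kb apart, the one with the most was on chromosome 8, from 121841303 to 121852866, where 4 of 5 peaks between the end of the predicted gene Gm42048 and the long non-coding RNA gene Gm26812 were lower, with log2 folds from -2.05 to -0.69 in the authors' deposited table. Klhdc4 also lay in or within 20 kb of this run. The Slc7a5 peak given above lies farther up the same chromosome, at 121898475 to 121898875. The lower peaks of the run were not assigned to Slc7a5, and a link to it was not tested. Another run of 3 lower peaks among 4, from 37272361 to 37284338 of chromosome 3, lay in an intergenic stretch nearest Cetn4, and one of 3 among 4 lay beside Il12rb2, an interleukin-12 receptor gene. From 64301077 to 64305937 of chromosome 1, 3 of 3 peaks nearest Klf7 were lower within 4.86 kb, and from 106588454 to 106617384, at Bcl2, 3 of 8 were.

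A hypothesis that early activation genes also lose accessibility away from their ends was tested on the peaks assigned to them outside the gene-end class. Of these 266 peaks 12 (4.51%) were lower, against a central range of 0.376% to 3.38% for random sets of like signal. The permutation p was 0.004 before and 0.064 after adjustment over 16 lists, so the result fails the correction. The effector list had 9 lower of 205 such peaks (4.39%), with an adjusted permutation p of 0.24.

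The 4 higher peaks at Cd4 formed a run of 20.7 kb, and CD4 T cells among the KO cells would raise other genes of that lineage too. The 82 peaks of the 9 other listed CD4 and regulatory T cell genes had a median log2 difference of -0.17 with none called higher and a highest difference of 0.50, at Cd40lg. Of the CD8 lineage genes, Cd8a had a median of -0.24 over 11 peaks with 1 called lower, and Cd8b1 -0.13 over 15 with none; the change a small share would give is unknown without CD4 T cell libraries, so such cells stay open. Another candidate explanation is Cd4 sequence carried by the Cd4-Cre transgene and counted at the native gene: 0 uncalled peaks lay between the first and last raised peak, but that run was what prompted the idea, so it lends no support. The transgene separates KO from WT by design, and an effect of ATF4 loss on Cd4 itself also stays open as untested.

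The 6 higher peaks beside Atf4 were 6 of 19 in the genome. In 10000 draws of 19 peaks of like signal no 100 kb window held more than 3 (permutation p = 0.0001, the smallest the draws can give), which argues against unrelated peaks falling together by chance. Extra copies of the whole region would raise every peak in it, but an uncalled peak among them had a log2 difference of 0.0118, with an upper 95% bound of 0.40 from the spread implied by its p, against at least 1.26 at the raised peaks. Whether the rise follows from the Cre-deleted allele in cis or from loss of the protein is open, since both go with genotype.

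The excess of lower calls was set against scaling. A uniform offset between the genotypes, as the only source of the excess, would leave higher and lower calls about equal after centring. Yet higher calls made up 17.6% of calls after the median was subtracted. An offset beside other sources of lower calls is not excluded, and 437 of the 639 lower calls ended in this step. Removing the trend of the difference with peak signal kept 138 lower calls against 45 higher, which argues against a trend with signal alone as the cause of those 138. A technical difference that varies among peaks of like signal is not removed by this step, so it stays open for them too. For the other 501 lower calls a technical trend, such as a difference in enrichment between libraries, cannot be told apart from a real fall at weaker, gene-distal peaks, because values per library were not analysed here. A lost call does not mean that the fall was removed. The medians of the 10 signal classes ran from -0.25 to 0.04, while all 639 lower peaks had a median log2 difference of -0.96.

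The called gene-end peak of Pgk1 had the highest WT mean of the 639 lower peaks, with 2369 normalized reads, and 1225 in KO. The next Pgk1 peak had a log2 difference of -0.39 and was not called (FDR 0.44 in the authors' deposited table).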
